A study of Homo sapiens with 6 samples.

How the data were processed

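RNA-seq was carried out on MCF-7 cells, an estrogen receptor-positive human breast adenocarcinoma line, in 3 groups of 2 libraries: DMSO vehicle, 300 nM GDC-9545 and 300 nM GNE-858, all for 24 h. Groups and replicate numbers were taken from the sample labels. GDC-9545 is giredestrant, an oral antagonist and degrader of the estrogen receptor. GNE-858 is known here by its code name alone, and nothing was assumed about it. Per the labels' protocols, the cells were kept in RPMI medium with serum, which is not said to be stripped of hormones, and RNA was extracted from duplicates with a column kit. The labels' protocols name 2 library kits, one for poly(A) RNA and one for total RNA, and which kit served which library is not given in the sources used here.

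The deposited table held raw counts of reads per gene, as whole numbers without normalization, for 58302 Ensembl gene identifiers in 6 library columns. Per the submitters' processing notes, reads were aligned with GSNAP to GRCh38. The GSNAP version, the counting program, the gene annotation and the use of strand are not given in the sources used here. A gene that overlaps another was therefore treated as uncertain when the other held at least 10% of its counts. Symbols were found for 57532 of the identifiers and positions for 58039 of them in GENCODE 29, which uses GRCh38. At total count 0 in every library were 26542 identifiers. Total counts per library lay between 53892979 and 65370069.

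Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in R 4.3.3, after filterByExpr, which kept 19016 genes, and TMM scaling. All 6 libraries entered a single fit with a term per group and no covariate, which left 3 residual degrees of freedom, supplemented by 7.10 prior degrees of freedom. The biological coefficient of variation was 0.0708. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors were obtained from the log2 fold change and its F statistic, and 95% intervals from the moderated degrees of freedom. Levels are given as TMM-scaled CPM. The comparisons were GDC-9545 against DMSO, GNE-858 against DMSO and GNE-858 against GDC-9545 at the same dose and time.

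The groups, the tests, 28 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered estrogen-induced and estrogen-repressed genes, luminal epithelial genes, basal and mesenchymal genes, stromal, endothelial and blood genes, DNA replication, mitosis, cholesterol synthesis, fatty acid synthesis, cholesterol efflux, endoplasmic reticulum stress, ATF4 stress genes, heat shock genes, interferon-stimulated genes, aryl hydrocarbon receptor targets, PXR and CAR targets, NRF2 targets, p53 targets, glucocorticoid, progestin and androgen targets, retinoic acid targets, ERK feedback genes, hypoxia and glycolysis, cytosolic ribosomal proteins, ribosome biogenesis, lysosome, nuclear oxidative phosphorylation, mitochondrially encoded genes and RNAs without a poly(A) tail. Of the list members, 602 of 603 were matched. The PXR and CAR list had fewer than 5 members expressed and was not tested. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were alternatives.

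Named genes were chosen by rule. For each comparison, the rule took the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 1, no overlap between the libraries of the groups and an official symbol of neither a ribosomal, small non-coding, antisense, clone nor pseudogene kind. It added up to 4 members, by smallest p, of each list that was called or had 3 or more called members. It also added ESR1, PGR, GREB1, TFF1, CCND1, MYC, MKI67, CYP1A1, HMGCS1 and LDLR whatever their values. Genes outside the rule are marked in the text as chosen after their values were seen.

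Alternatives were DESeq2 size factors or upper-quartile factors in edgeR, no filter on low counts, a stricter filter (1 CPM in 2 libraries and a mean of 50 counts), DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, the replicate number as a block, thinning to the smallest library, a minimum fold of 1.5 (glmTreat), a threshold of 0.01 and leaving out each library. In a fit without 1 library, the lone library of its group was assumed to vary like the other groups. Added after seeing the data were an offset for GC content and transcript length, fitted per library with mgcv 1.9.3, and limma-voom with library quality weights. The DMSO libraries served both compounds, so 20 pairs of unchanged groups were simulated against them. The DMSO pair cannot be split into parts of 2 libraries.

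The procedure was tested on simulated counts. In simulated libraries for GDC-9545 against DMSO (18398 genes), 10% of 50 genes changed 1.2-fold were called, 46% at 1.5-fold, 66% at 2-fold and 80% at 4-fold. Of 18171 unchanged genes, 6 were called. Among the changed genes that were tested, 95.9% of the 95% intervals held the true value. Coverage was not computed for the unchanged genes. In simulated libraries for GNE-858 against DMSO without any effect, edgeR called 0 genes and camera 0 lists. Each gene was drawn independently, so the list result cannot show how camera performs when the genes of a list are correlated. All groups were drawn with the same spread per gene and without a GC trend, unlike the real replicate pairs. The simulation therefore cannot show whether p-values hold when the spread differs between groups.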

Results

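Gene-level RNA-seq counts were collected from MCF-7 breast cancer cells, which grow in response to estrogen, after 24 h with DMSO, 300 nM GDC-9545 or 300 nM GNE-858 (n = 2 libraries per group). GDC-9545, or giredestrant, is an oral estrogen receptor antagonist and degrader. Total counts were 58992857 and 61170513 for DMSO, 58539696 and 53892979 for GDC-9545, and 65370069 and 64952054 for GNE-858. Between 25063 and 25947 genes had a count in a library. Protein-coding genes took 97.4 to 97.5% of counts in every library, and the 100 highest genes 15.7 to 16.4%. The counts of each replicate pair differed by more than sampling noise, with a chi-square per gene of 3.72 for DMSO, 9.45 for GDC-9545 and 23.4 for GNE-858, against 26.9 to 81.0 for pairs from different groups. The first principal component held 42.3% of the variance and the second 21.5%. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Of the genes named, EGR3, AGR3, AHRR, CRELD2, PRSS23, PSCA, SLC4A10 and LDLR overlap another gene, pseudogene or antisense gene with counts of its own. MUC3A belongs to a family of similar mucins. The values of all these genes are uncertain.

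The first comparison asked which transcripts differed between GDC-9545 and vehicle. Genes known to be induced by estrogen fell with GDC-9545. GREB1, a coactivator that binds the estrogen receptor, went from 716 ± 6.56 CPM with DMSO to 49.4 ± 1.00 CPM (mean ± SD, n = 2), a 14.5-fold fall, and PGR, the progesterone receptor gene, from 36.8 ± 3.17 to 4.13 ± 0.174 CPM, an 8.91-fold fall. TFF1, which encodes a secreted trefoil peptide, fell 2.70-fold from 1163 ± 4.36 to 431 ± 7.34 CPM, and CCND1, the cyclin D1 gene, fell 1.99-fold from 1024 ± 18.0 to 513 ± 15.8 CPM. Genes known to be repressed by estrogen rose, among them IL1R1, the interleukin-1 receptor gene, which went from 6.47 ± 0.10 to 39.4 ± 1.46 CPM, a 6.09-fold rise.

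The log2 fold changes with GDC-9545 were -3.86 ± 0.06 for GREB1 (SE; adjusted p = 4.74e-10, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), -3.16 ± 0.14 for PGR (edgeR adjusted p = 2.62e-07) and -1.43 ± 0.07 for TFF1 (edgeR adjusted p = 5.48e-07), and the edgeR adjusted p of CCND1 was 1.01e-06. GREB1 (ENSG00000196208) lies on chromosome 2 from 11482341 to 11642788 in GRCh38, PGR (ENSG00000082175) on chromosome 11 from 101029624 to 101130524 and TFF1 (ENSG00000160182) on chromosome 21 from 42362282 to 42366594. CCND1 (ENSG00000110092) lies on chromosome 11 from 69641087 to 69654474, and values are counts over each whole gene. MYC, a growth-promoting transcription factor gene (ENSG00000136997, chromosome 8 from 127735434 to 127741434), fell 2.53-fold, by 1.34 ± 0.08 on the log2 scale. STC2, which encodes the secreted glycoprotein stanniocalcin 2, fell 4.88-fold and CXCL12, a chemokine gene, 8.28-fold. Of 52 estrogen-induced genes measured, 49 fell and 1 rose, and 49 and 1 did so adjusted over the list alone. The list's median log2 fold change was -1.15 (camera adjusted p = 1.23e-147), and the call held with an estimated correlation (adjusted p = 0.00302). The riser was P2RY2, a nucleotide receptor gene, at 0.24 ± 0.07, and ABCA3 (0.00 ± 0.06) and WFS1 (-0.10 ± 0.11) did not pass, a trio chosen after their values were seen. Without DMSO replicate 1, DMSO replicate 2 or GDC-9545 replicate 2, the adjusted p of P2RY2 was 0.138, 0.163 or 0.192.

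Of 12 estrogen-repressed genes, 11 rose and 1 fell with GDC-9545, with the same counts of 11 and 1 adjusted over the list alone and a median log2 fold change of 1.13 (camera adjusted p = 6.76e-33, and adjusted p = 0.00926 with an estimated correlation). Besides IL1R1 (2.61 ± 0.10), the risers held the proapoptotic genes BMF (1.86 ± 0.07) and BAK1 (1.18 ± 0.06) and the growth inhibitor BTG2 (1.48 ± 0.06). KLF4, a transcription factor gene, was the member that fell, by 0.63 ± 0.08, and was picked out after its value was seen. ESR1, the estrogen receptor alpha gene (ENSG00000091831, chromosome 6 from 151656691 to 152129619), was at 312 ± 1.46 CPM with DMSO and 373 ± 13.8 CPM with GDC-9545, a log2 difference of 0.26 ± 0.05 (edgeR adjusted p = 0.00400). That call was lost without DMSO replicate 1 (0.25, adjusted p = 0.0678) or DMSO replicate 2 (0.27, adjusted p = 0.0589).

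**Figure D1:**
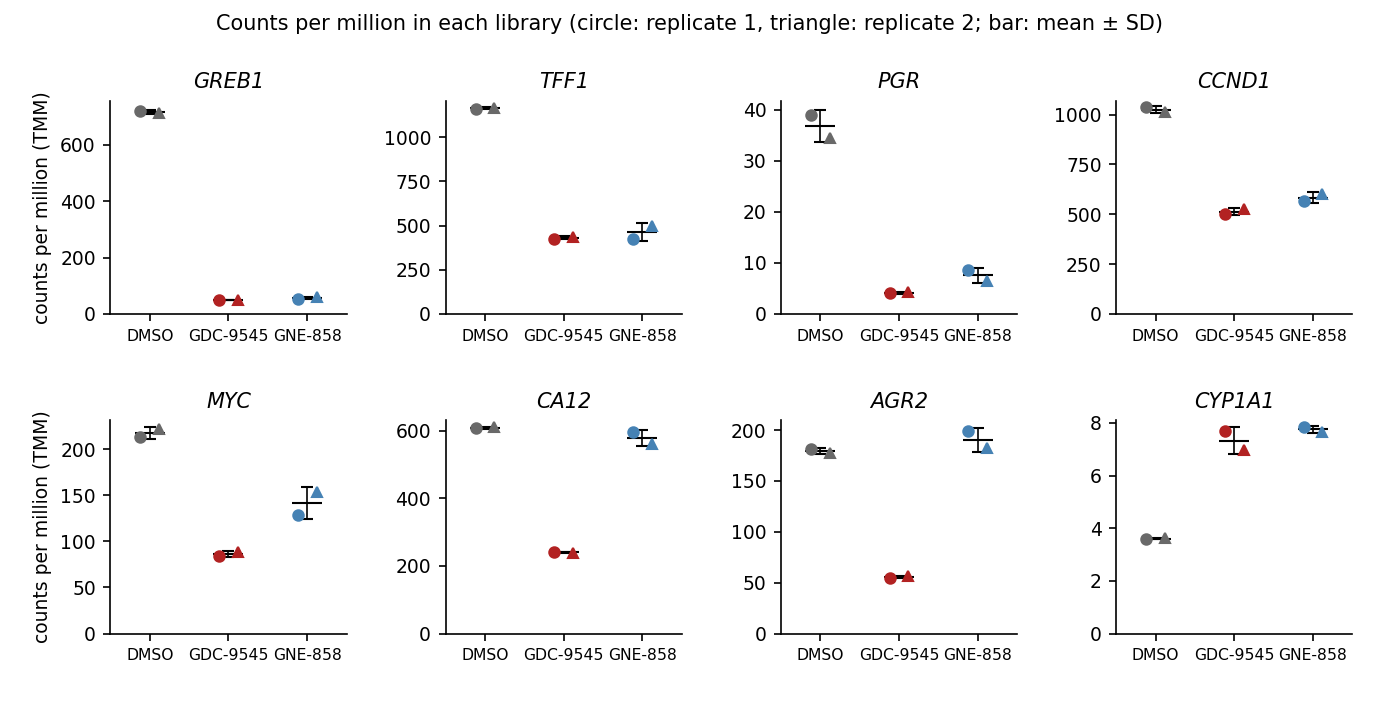
CPM (TMM-scaled counts, linear axes from 0) of 8 genes in each of the 6 libraries, with circles for replicate 1, triangles for replicate 2, and the mean ± SD of each group as a bar. GREB1 lay near 716 CPM with DMSO and at 49.4 and 56.6 CPM with GDC-9545 and GNE-858, whereas CA12 lay at 240 CPM with GDC-9545 and 578 CPM with GNE-858.

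The largest called falls with GDC-9545 were in PDZK1, which encodes a membrane scaffold protein (30.9-fold, from 6.02 ± 0.724 to 0.190 ± 0.112 CPM), RAMP3, which encodes a receptor-modifying protein (23.6-fold, from 19.5 ± 0.180 to 0.822 ± 0.122 CPM), CDH26, a cadherin gene (-4.54 ± 0.21), AGR3 (-4.24 ± 0.22) and EGR3, an immediate early transcription factor gene (16.9-fold). Also among the 10 largest falls were RBM24 (-3.53 ± 0.30), ATRNL1 (-3.38 ± 0.17) and the bicarbonate transporter gene SLC4A10 (-3.32 ± 0.34). The largest rises were in MUC3A (2.64 ± 0.09), IL1R1, the acetylcholinesterase gene ACHE (2.52 ± 0.13), AFF2 (2.46 ± 0.23) and the sialyltransferase gene ST6GAL1 (2.24 ± 0.15). MAB21L4 (2.23 ± 0.14), the transcription factor gene SALL4 (2.19 ± 0.10), the endocytic receptor gene LRP2 (2.14 ± 0.17), PSCA (2.14 ± 0.21) and TNFSF10, which encodes the death ligand TRAIL (2.12 ± 0.14), completed the 10. In total 5242 of 19016 genes differed, 2485 higher and 2757 lower, of which 392 and 339 by over 2-fold (edgeR quasi-likelihood test). The count was 2754 without DMSO replicate 1, 2740 without DMSO replicate 2, 3138 at a threshold of 0.01 and 508 when a fold above 1.5 was tested.

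Genes of cell growth and division fell with GDC-9545. Of 35 DNA replication genes, 34 fell (34 adjusted over the list alone). The median was -0.79 (camera adjusted p = 4.3e-46, and adjusted p = 0.00871 with an estimated correlation). They held the helicase subunit gene MCM7, which went from 807 ± 25.2 to 439 ± 2.35 CPM, and PCNA, the polymerase clamp gene (-0.84 ± 0.05). All 26 ribosome biogenesis genes fell (26 adjusted over the list alone), among them the nucleolar genes DDX21 (-0.79 ± 0.05) and NOLC1 (-0.76 ± 0.05). The median was -0.63 (camera adjusted p = 6.36e-24, and adjusted p = 0.00953 with an estimated correlation). Of 30 mitosis genes, 28 fell (28 adjusted over the list alone). The median was -0.29 (camera adjusted p = 4.77e-09). That call was lost with an estimated correlation (adjusted p = 0.197), and 13, 12 and 16 members fell without DMSO replicate 1, DMSO replicate 2 and GDC-9545 replicate 2. The mitotic kinase gene CDK1 fell by 0.54 ± 0.06 and the proliferation marker MKI67 by 0.46 ± 0.07, from 289 ± 10.5 to 210 ± 12.1 CPM.

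Of 24 cholesterol synthesis genes, 17 fell and 1 rose with GDC-9545 (17 and 1 adjusted over the list alone). The median was -0.38 (camera adjusted p = 5.39e-06, and adjusted p = 0.0700 with an estimated correlation). The squalene epoxidase gene SQLE fell by 0.48 ± 0.05 and the HMG-CoA synthase gene HMGCS1 by 0.48 ± 0.06, while the LDL receptor gene LDLR was at -0.10 ± 0.05 (edgeR adjusted p = 0.195, and 0.00147 at -0.17 with the GC content and length offset). Of 15 fatty acid synthesis genes, 7 fell (7 adjusted over the list alone), including the elongase gene ELOVL5 (-0.71 ± 0.06). The median was -0.20 (camera adjusted p = 0.0108, and adjusted p = 0.161 with an estimated correlation). 4 of them fell without DMSO replicate 1, DMSO replicate 2 or GDC-9545 replicate 2. Of 8 cholesterol efflux genes, 3 rose (5 adjusted over the list alone). The median was 0.34 (camera adjusted p = 0.000827, and adjusted p = 0.115 with an estimated correlation). ABCG1, a sterol transporter gene, rose by 1.11 ± 0.07. Of 17 endoplasmic reticulum stress genes, 10 fell and 1 rose (11 and 1 adjusted over the list alone). The median was -0.36 (camera adjusted p = 0.000827, and adjusted p = 0.115 with an estimated correlation). The chaperone genes HSPA5 (-0.43 ± 0.05) and PDIA4 (-0.44 ± 0.05) were among those that fell. Of 12 heat shock genes, 7 fell (8 adjusted over the list alone). The median was -0.32 (camera adjusted p = 0.000874, and adjusted p = 0.115 with an estimated correlation). HSPA8, a constitutive chaperone gene, fell by 0.51 ± 0.05.

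Among signaling and stress lists, 8 of 15 ERK feedback genes fell with GDC-9545 and 4 rose (9 and 4 adjusted over the list alone). The median was -0.66 (camera adjusted p = 0.00355, and adjusted p = 0.132 with an estimated correlation). The immediate early gene FOS fell by 1.62 ± 0.10 and the phosphatase gene DUSP5 by 1.05 ± 0.11, and 1, 1 and 1 members rose without DMSO replicate 1, DMSO replicate 2 and GDC-9545 replicate 2, against 2 without GDC-9545 replicate 1. Of 27 interferon-stimulated genes, 9 rose (10 adjusted over the list alone). The median was 0.29 (camera adjusted p = 0.000827, and adjusted p = 0.20 with an estimated correlation). The antiviral genes OAS1 (0.84 ± 0.11) and MX1 (0.59 ± 0.10) were among them, and 5, 4, 14 and 14 rose without DMSO replicate 1, DMSO replicate 2, GNE-858 replicate 1 and GNE-858 replicate 2. Of 18 ATF4 stress genes, 8 fell and 2 rose (8 and 3 adjusted over the list alone). The median was -0.20 (camera adjusted p = 0.0195, and adjusted p = 0.328 with an estimated correlation). The mitochondrial folate enzyme gene MTHFD2 fell by 0.71 ± 0.06 and DDIT4, an inhibitor of mTOR, rose by 0.73 ± 0.10. Without GDC-9545 replicate 1, 5 members fell, and 1 rose without DMSO replicate 1, DMSO replicate 2, GDC-9545 replicate 1 or GDC-9545 replicate 2.

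Of 5 aryl hydrocarbon receptor targets, 2 rose and 2 fell with GDC-9545 (3 and 2 adjusted over the list alone). The median was 1.02 (camera adjusted p = 0.0336, and adjusted p = 0.257 with an estimated correlation). CYP1A1, a cytochrome P450 gene, rose 2.03-fold from 3.61 ± 0.0355 to 7.32 ± 0.518 CPM and the receptor repressor gene AHRR rose by 1.53 ± 0.09, whereas TIPARP, which encodes an ADP-ribosyltransferase, fell by 0.56 ± 0.10. The list's camera adjusted p was 0.0588, 0.0956, 0.0727 and 0.0720 without DMSO replicate 1, GDC-9545 replicate 1, GNE-858 replicate 1 and GNE-858 replicate 2, and 1 member fell without DMSO replicate 1, DMSO replicate 2 or GDC-9545 replicate 2. The call was also lost with no filter (adjusted p = 0.160), a replicate block (0.0770), DESeq2 (0.0564), limma-voom (0.0588, and 0.0709 with quality weights) and the GC content and length offset (0.115). Of 8 retinoic acid targets, 5 rose and 2 fell (5 and 2 adjusted over the list alone). The median was 0.77 (camera adjusted p = 0.0386, and adjusted p = 0.218 with an estimated correlation). The retinol transporter gene STRA6 rose by 1.25 ± 0.09 and the retinoic acid hydroxylase gene CYP26B1 fell by 1.68 ± 0.29. That list's camera adjusted p was 0.0728, 0.0730, 0.140 and 0.0600 without DMSO replicate 1, DMSO replicate 2, GDC-9545 replicate 2 and GNE-858 replicate 2, and 3 members rose without DMSO replicate 1. It was 0.0591 with no filter, 0.0693 with the stricter filter, 0.0914 with a replicate block, 0.0564 with DESeq2 and 0.115 with the offset.

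Mitochondrially encoded transcripts rose with GDC-9545 in 12 of 13 members (12 adjusted over the list alone). The median was 0.48 (camera adjusted p = 5.22e-06, and adjusted p = 0.257 with an estimated correlation), and 5 rose without DMSO replicate 1. The mitochondrial share of counts was 0.917 and 1.04% in the DMSO libraries, 1.38 and 1.48% with GDC-9545 and 1.40 and 1.11% with GNE-858. The cytochrome c oxidase gene MT-CO1 rose by 0.52 ± 0.08 with GDC-9545. Among 28 nuclear genes of oxidative phosphorylation, 7 fell (7 adjusted over the list alone), such as the ATP synthase gene ATP5F1B (-0.29 ± 0.04). The median was -0.12 (camera adjusted p = 0.0196, and adjusted p = 0.257 with an estimated correlation). Without DMSO replicate 1 or 2, 4 of them fell, and without GDC-9545 replicate 2, 4 fell and the list's camera adjusted p was 0.0541, against 12 without GNE-858 replicate 1 or 2. That adjusted p was 0.0561 with the stricter filter and 0.0761 with the GC content and length offset. Of 13 genes on the list of RNAs without a poly(A) tail, most of them histone genes, 9 rose (9 adjusted over the list alone). The list goes by gene, and whether the transcripts counted had a tail was not tested. The median was 0.74 (camera adjusted p = 9.62e-07, and adjusted p = 0.197 with an estimated correlation). The histone gene H2BC21 rose by 0.94 ± 0.05. Of 74 cytosolic ribosomal protein genes, 6 fell (1 adjusted over the list alone). The median was -0.12 (camera adjusted p = 0.0196, and adjusted p = 0.482 with an estimated correlation). Their number was at most 2 without DMSO replicate 1 or DMSO replicate 2, 3 without either GDC-9545 library and 29 without either GNE-858 library. The stricter filter (adjusted p = 0.0693), the offset (adjusted p = 0.104) and fry (adjusted p = 0.110) ended the list's call.

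Of the cell type lists, 1 was called with GDC-9545. Of 21 luminal epithelial genes, 8 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.15, camera adjusted p = 0.159), and AGR2, a disulfide isomerase gene of secretory cells, fell from 179 ± 3.06 to 55.6 ± 1.24 CPM. ERBB3, a growth factor receptor gene, rose by 0.60 ± 0.05. Of 12 basal and mesenchymal genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone; median 0.11, camera adjusted p = 0.791). Of 5 stromal, endothelial and blood genes with enough counts, 3 rose (3 adjusted over the list alone). The median was 0.87 (camera adjusted p = 0.0180, and adjusted p = 0.234 with an estimated correlation). That call was lost with limma-voom (adjusted p = 0.0547, and 0.0582 with quality weights) and with the GC content and length offset (adjusted p = 0.0957), and 1 member rose without DMSO replicate 2 or GDC-9545 replicate 2. The endothelial cadherin gene CDH5 went from 0.295 ± 0.0290 to 1.82 ± 0.208 CPM. Not called by camera were NRF2 targets (1 rose and 4 fell of 18, and 1 and 4 adjusted over the list alone; adjusted p = 0.164), p53 targets (6 rose and 1 fell of 19, and 6 and 2 adjusted over the list alone; adjusted p = 0.126), and glucocorticoid, progestin and androgen targets (4 rose and 2 fell of 10, and 4 and 2 adjusted over the list alone; adjusted p = 0.138). Lysosome genes (9 rose and 1 fell of 22, and 10 and 1 adjusted over the list alone; adjusted p = 0.138) and hypoxia and glycolysis genes (3 rose and 12 fell of 21, and 3 and 12 adjusted over the list alone; adjusted p = 0.0861) did not pass either. With no filter camera called luminal genes (adjusted p = 0.0125), NRF2 targets (0.0289), hypoxia and glycolysis genes (0.00279) and lysosome genes (0.0154). Fry called NRF2 targets (0.0199), p53 targets (0.0102), glucocorticoid, progestin and androgen targets (0.00419), hypoxia and glycolysis genes (0.00492) and lysosome genes (0.0156). Numbers that rose and fell also changed when 1 library was left out, which changes the shared estimate of spread too. They were 2 and 1 for p53 targets and for lysosome genes without DMSO replicate 1. Without DMSO replicate 2 they were 1 and 1 for NRF2, 3 and 1 for p53, 2 and 5 for hypoxia and 3 and 1 for lysosome genes, and the 4 basal and mesenchymal calls were lost. Without GDC-9545 replicate 1 they were 0 and 2 for basal, 2 and 6 for hypoxia and 3 and 1 for lysosome genes, and without GDC-9545 replicate 2 they were 1 and 1 for basal, 1 and 2 for NRF2, 3 and 6 for hypoxia and 5 and 1 for lysosome genes. Without either GNE-858 replicate 1 or GNE-858 replicate 2 they were 1 and 7 for NRF2, 7 and 4 for p53 and 11 and 2 for lysosome genes. Members of these lists that changed included the lactate dehydrogenase gene LDHA (-0.72 ± 0.05) and the cystine transporter gene SLC7A11 (-1.26 ± 0.13). The steroid receptor co-chaperone gene FKBP5 (-0.72 ± 0.06) was 1 of the 2 that fell in its list, where 4 rose. The nuclease gene AEN (-0.80 ± 0.05) was the only p53 target called lower, against 6 that rose. The lysosomal galactosidase gene GLA (-0.98 ± 0.06) was the only lysosome gene called lower, against 9 that rose.

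**Figure D2:**
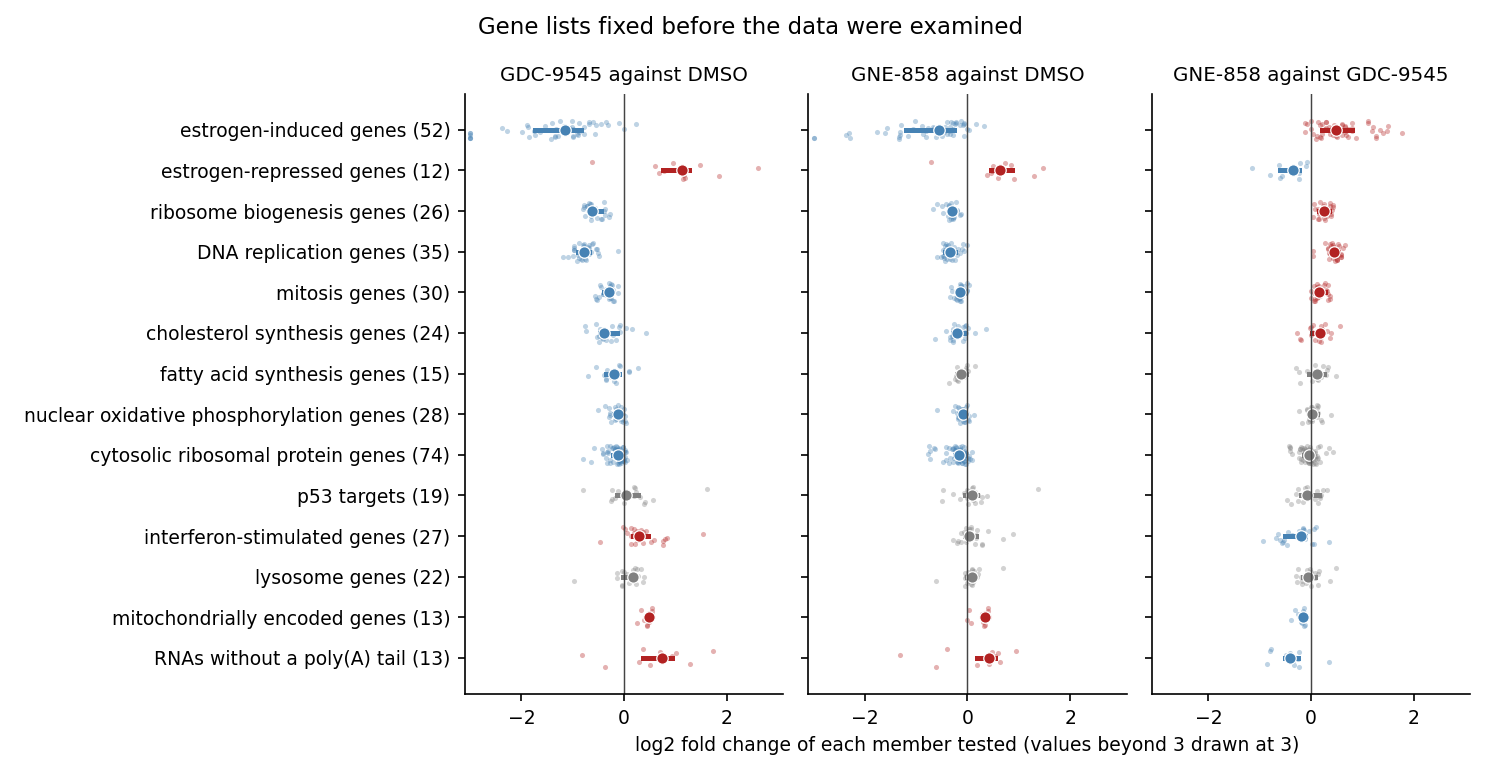
Log2 fold changes of the tested members of 14 gene lists (dots) in the 3 comparisons, with each list's median (large dot) and quartiles (bar), and the number tested in brackets. Blue marks lists called lower and red lists called higher by camera at the preset correlation of 0.01, grey those not called, and the estrogen-induced list lies at medians of -1.15, -0.56 and 0.48 from left to right.

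The second comparison asked which transcripts differed between GNE-858 and vehicle. Estrogen-induced genes fell with GNE-858 too. GREB1 fell 12.7-fold to 56.6 ± 3.46 CPM (log2 fold change -3.66 ± 0.06, edgeR adjusted p = 7.09e-10), PGR 4.88-fold to 7.54 ± 1.46 CPM (-2.29 ± 0.13, edgeR adjusted p = 6.47e-06), TFF1 2.52-fold to 463 ± 51.6 CPM (-1.33 ± 0.07, edgeR adjusted p = 4.51e-06) and CCND1 1.75-fold to 584 ± 26.4 CPM (-0.81 ± 0.05, edgeR adjusted p = 1.6e-05). MYC fell 1.54-fold to 141 ± 17.7 CPM. Of the 52 estrogen-induced genes, 40 fell (43 fell and 1 rose adjusted over the list alone). The median was -0.56 (camera adjusted p = 2e-101, and adjusted p = 0.00472 with an estimated correlation). The growth factor-binding gene IGFBP4 fell by 1.17 ± 0.05. Of the 12 estrogen-repressed genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone). The median was 0.64 (camera adjusted p = 5.38e-23, and adjusted p = 0.0194 with an estimated correlation). BMF rose by 1.29 ± 0.06, the cyclin G2 gene CCNG2 by 0.91 ± 0.06 and IL1R1 by 1.46 ± 0.10, to 17.8 ± 2.12 CPM, while KLF4 fell by 0.71 ± 0.08. ESR1 was at 347 ± 8.19 CPM, 0.15 ± 0.05 above DMSO (edgeR adjusted p = 0.0698, and 0.0192 at 0.18 without GNE-858 replicate 2).

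The largest called falls with GNE-858 were in PDZK1 (12.8-fold, to 0.468 ± 0.0408 CPM), GREB1, the serine protease gene PRSS23 (-2.43 ± 0.06), CXCL12 (5.18-fold) and the long non-coding RNA PRADX (-2.35 ± 0.22), which overlaps CTSD and is uncertain. EGR3 (4.94-fold), PGR, RBM24 (-2.25 ± 0.26), the membrane glycoprotein gene IGSF1 (-2.08 ± 0.07) and TENM4 (-2.05 ± 0.12) followed. The largest rises were in the transcription factor gene SIM1 (4.70-fold, from 1.17 ± 0.0563 to 5.51 ± 0.553 CPM), TNFSF10 (3.80-fold), the long non-coding RNA FAM30A (1.65 ± 0.14), AFF2 (1.65 ± 0.24), the neprilysin gene MME (1.64 ± 0.19) and SALL4 (2.92-fold). MUC3A (1.48 ± 0.09), IL1R1, the proton pump gene ATP6V0A4 (1.46 ± 0.13) and MAB21L4 (1.41 ± 0.15) completed the 10. In total 2843 genes differed, 1493 higher and 1350 lower, of which 105 and 153 by over 2-fold (edgeR quasi-likelihood test). The count was 649 and 567 without DMSO replicates 1 and 2, 4574 without GNE-858 replicate 2, 4793 with the GC content and length offset, 992 at a threshold of 0.01 and 103 when a fold above 1.5 was tested.

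DNA replication genes fell in 25 of 35 members with GNE-858 (30 adjusted over the list alone). The median was -0.34 (camera adjusted p = 1.1e-17, and adjusted p = 0.0194 with an estimated correlation). MCM7 fell by 0.46 ± 0.05, to 587 ± 13.5 CPM, and the initiation factor gene CDC45 by 0.48 ± 0.06. Ribosome biogenesis genes fell in 24 of 26 members (25 adjusted over the list alone), such as NOLC1 (-0.38 ± 0.05). The median was -0.31 (camera adjusted p = 4.71e-15, and adjusted p = 0.0194 with an estimated correlation). Without DMSO replicate 1 and DMSO replicate 2, respectively, 11 and 9 replication genes and 6 and 6 biogenesis genes fell. Of 30 mitosis genes, 8 fell (12 adjusted over the list alone). The median was -0.14 (camera adjusted p = 0.000276, and adjusted p = 0.321 with an estimated correlation). Their number was at most 1 without DMSO replicate 1 or DMSO replicate 2, 5 without GDC-9545 replicate 1 and 14 without GNE-858 replicate 1. MKI67 was at 266 ± 18.1 CPM, -0.12 ± 0.06 from DMSO (edgeR adjusted p = 0.238, and 0.00265 at -0.21 with the GC content and length offset).

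Among the stress and lipid lists, 11 of 17 endoplasmic reticulum stress genes fell with GNE-858 (11 fell and 3 rose adjusted over the list alone). The median was -0.27 (camera adjusted p = 0.000437, and adjusted p = 0.119 with an estimated correlation). Among those that fell were HSPA5 (-0.42 ± 0.05) and the secreted folding factor genes MANF (-0.44 ± 0.06) and CRELD2 (-0.55 ± 0.07). Of 18 ATF4 stress genes, 9 fell and 1 rose (9 and 1 adjusted over the list alone). The median was -0.21 (camera adjusted p = 0.00119, and adjusted p = 0.294 with an estimated correlation). The serine synthesis gene PHGDH fell by 0.43 ± 0.06. Cholesterol synthesis genes fell in 11 of 24 members and rose in 1 (13 and 1 adjusted over the list alone). The median was -0.20 (camera adjusted p = 0.000293, and adjusted p = 0.118 with an estimated correlation). Heat shock genes fell in 5 of 12 (6 adjusted over the list alone). The median was -0.19 (camera adjusted p = 0.00619, and adjusted p = 0.198 with an estimated correlation). HMGCS1 fell by 0.29 ± 0.06, with an edgeR adjusted p of 0.0131 that was 0.146 without DMSO replicate 1 and 0.104 without DMSO replicate 2, and LDLR was at -0.09 ± 0.05 (edgeR adjusted p = 0.262, and 0.0155 at -0.13 with the GC content and length offset). Without DMSO replicate 1, 3 endoplasmic reticulum stress genes and 2 ATF4 stress genes fell, and without DMSO replicate 2, 4 and 2. At most 1 cholesterol synthesis gene and 1 heat shock gene fell without either DMSO library, and the calls of the ATF4 and the cholesterol synthesis gene that rose were lost. The ATF4 call was lost without GNE-858 replicate 2 too, and 2 cholesterol synthesis genes rose without GNE-858 replicate 1. Fatty acid synthesis genes fell in 4 of 15 members (5 adjusted over the list alone; median -0.13, camera adjusted p = 0.0620, and 0.0181 without GNE-858 replicate 1), and cholesterol efflux genes rose in 3 of 8 (3 adjusted over the list alone; median 0.08, camera adjusted p = 0.0983). The calls of these members were lost without either DMSO library. Fatty acid synthesis genes were called by camera with the GC content and length offset (adjusted p = 0.00148), no filter (0.00738), a replicate block (0.0445), DESeq2 (0.0313) and limma-voom (0.0280, and 0.0156 with quality weights), and by fry (0.000965). Cholesterol efflux genes were called with no filter (0.0398) and by fry (0.00947).

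CYP1A1 rose 2.15-fold to 7.76 ± 0.123 CPM with GNE-858, and AHRR by 0.95 ± 0.09, the 2 of 5 aryl hydrocarbon receptor targets that rose (2 rose and 1 fell adjusted over the list alone). The median was 0.15 (camera adjusted p = 0.0213, and adjusted p = 0.294 with an estimated correlation). The list's camera adjusted p was 0.0670, 0.0505 and 0.0541 without DMSO replicate 1, GNE-858 replicate 1 and GNE-858 replicate 2, 0.153 with no filter, 0.0515 with a replicate block and 0.105 with the GC content and length offset. Of 8 retinoic acid targets, 3 rose, STRA6 by 0.80 ± 0.09, and 1 fell (4 and 1 adjusted over the list alone). The median was 0.37 (camera adjusted p = 0.0112, and adjusted p = 0.251 with an estimated correlation). The stricter filter ended that call (adjusted p = 0.0626), and 1 member rose without DMSO replicate 1 or DMSO replicate 2. The call of the member that fell was lost without DMSO replicate 1, DMSO replicate 2, GNE-858 replicate 1 or GNE-858 replicate 2. Mitochondrially encoded transcripts rose in 7 of 13 members (10 adjusted over the list alone). The median was 0.33 (camera adjusted p = 0.000379, and adjusted p = 0.332 with an estimated correlation), and at most 1 rose without DMSO replicate 1 or DMSO replicate 2. The mitochondrial share of counts was 1.40 and 1.11% in the GNE-858 libraries against 0.917 and 1.04% with DMSO. Nuclear oxidative phosphorylation genes fell in 4 of 28 members (7 adjusted over the list alone). The median was -0.09 (camera adjusted p = 0.00619, and adjusted p = 0.294 with an estimated correlation). Cytosolic ribosomal protein genes fell in 13 of 74 (28 adjusted over the list alone). The median was -0.16 (camera adjusted p = 3.26e-07, and adjusted p = 0.294 with an estimated correlation). Without DMSO replicate 1, DMSO replicate 2 and GNE-858 replicate 2, 1, 3 and 45 of them fell, beside 1, 1 and 11 nuclear oxidative phosphorylation genes, of which 2 fell without GDC-9545 replicate 1. RNAs without a poly(A) tail rose in 6 of 13 members, H2BC21 by 0.53 ± 0.05 (7 rose and 2 fell adjusted over the list alone). The median was 0.43 (camera adjusted p = 0.00280, and adjusted p = 0.321 with an estimated correlation), and 2 and 1 rose without DMSO replicates 1 and 2. Fry did not call the mitochondrially encoded (adjusted p = 0.113), ribosomal protein (0.0555) and poly(A)-lacking lists (0.0555).

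Camera called none of the remaining lists with GNE-858. Interferon-stimulated genes had 0 members past the edgeR test (0 adjusted over the list alone; median 0.03, adjusted p = 0.465), with 3 members at an unadjusted p under 0.05. ERK feedback genes rose in 2 and fell in 4 of 15 members (2 and 4 adjusted over the list alone; adjusted p = 0.121), with PHLDA1, a growth factor-induced gene, up by 0.56 ± 0.06 and FOS down by 1.02 ± 0.10. Luminal genes rose in 3 and fell in 1 of 21 (5 and 1 adjusted over the list alone; adjusted p = 0.20, and 0.0123 without GNE-858 replicate 1), with the trefoil factor gene TFF3 down by 1.18 ± 0.12, and basal and mesenchymal genes fell in 2 of 12 (2 adjusted over the list alone; adjusted p = 0.231). Stromal, endothelial and blood genes rose in 1 of 5 (2 adjusted over the list alone; adjusted p = 0.0721, and 0.0277 without DMSO replicate 2). The glucose transporter gene SLC2A1 rose by 0.43 ± 0.05 among hypoxia and glycolysis genes, of which 4 rose and 5 fell of 21 (4 and 6 adjusted over the list alone; adjusted p = 0.498). NRF2 targets rose in 1 and fell in 2 of 18 (1 and 2 adjusted over the list alone; adjusted p = 0.258), p53 targets rose in 2 and fell in 2 of 19 (5 and 3 adjusted over the list alone; adjusted p = 0.130, and 0.0460 without GNE-858 replicate 1), glucocorticoid, progestin and androgen targets rose in 3 and fell in 2 of 10 (3 and 2 adjusted over the list alone; adjusted p = 0.214), and lysosome genes rose in 2 and fell in 1 of 22 (2 and 1 adjusted over the list alone; adjusted p = 0.302). With the GC content and length offset camera called luminal genes (adjusted p = 0.0189) and p53 targets (0.0462). Fry called p53 targets (0.0220), glucocorticoid, progestin and androgen targets (0.0128) and ERK feedback genes (0.0127). Without DMSO replicates 1 and 2 all calls of NRF2 targets and of basal and mesenchymal genes were lost. The numbers that rose and fell without DMSO replicate 1 were 1 and 2 for ERK feedback, 1 and 1 for p53, 3 and 1 for glucocorticoid, progestin and androgen, 2 and 0 for hypoxia and 0 and 1 for lysosome genes. Without DMSO replicate 2 they were 1 and 1, 1 and 1, 2 and 1, 2 and 0, and 0 and 1 in the same order. Without GDC-9545 replicate 1 they were 0 and 2 for NRF2, 2 and 4 for hypoxia and 1 and 1 for lysosome genes, and without GDC-9545 replicate 2 they were 0 and 3, 2 and 4, and 0 and 1. Without GNE-858 replicate 1 they were 5 and 1 for luminal, 1 and 1 for NRF2 and 3 and 1 for p53 genes. Without GNE-858 replicate 2 they were 3 and 2 for interferon-stimulated, 6 and 4 for luminal, 2 and 6 for NRF2, 6 and 3 for p53, 1 and 4 for ERK feedback and 4 and 1 for lysosome genes.

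The third comparison set the compounds side by side at 300 nM and 24 h. Estrogen-induced genes were higher with GNE-858 than with GDC-9545, in 37 of 52 members (44 adjusted over the list alone). The median was 0.48 (camera adjusted p = 5.5e-63, and adjusted p = 0.00930 with an estimated correlation). CA12, a carbonic anhydrase gene (ENSG00000074410, chromosome 15 from 63321378 to 63382161), was at 578 ± 23.8 CPM with GNE-858 and 240 ± 0.931 CPM with GDC-9545, a 2.41-fold difference (1.27 ± 0.05, edgeR adjusted p = 6.26e-07). STC2 was 2.80-fold higher, GFRA1, a receptor gene for a neurotrophic factor, 2.16-fold, PGR 1.83-fold (0.87 ± 0.14) and MYC 1.64-fold (0.72 ± 0.08). AGR2, a luminal gene (ENSG00000106541, chromosome 7 from 16791811 to 16833433), was at 190 ± 11.6 CPM with GNE-858, 3.42-fold above GDC-9545 (1.78 ± 0.06, edgeR adjusted p = 2.53e-07).

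For 15 of the 52 estrogen-induced genes, GREB1 and TFF1 among them, no difference between the compounds was called. GREB1 differed by 0.20 ± 0.06 (95% interval 0.07 to 0.32, edgeR adjusted p = 0.0577), and by 0.26 (adjusted p = 0.00851) without GNE-858 replicate 1 and 0.22 (adjusted p = 0.00145) with the GC content and length offset. TFF1 differed by 0.10 ± 0.07 (95% interval -0.05 to 0.25, edgeR adjusted p = 0.393), and by 0.21 (adjusted p = 0.00848) without GNE-858 replicate 1 and 0.24 (adjusted p = 9.1e-05) with that offset. CCND1 was higher with GNE-858 by 0.19 ± 0.05 (edgeR adjusted p = 0.0482), and without DMSO replicate 1, DMSO replicate 2, GDC-9545 replicate 1 and GDC-9545 replicate 2 its adjusted p was 0.132, 0.142, 0.215 and 0.161. ESR1 differed by -0.10 ± 0.05 (95% interval -0.22 to 0.01, edgeR adjusted p = 0.232, and 0.00694 at -0.15 with the offset), and CYP1A1 by 0.08 ± 0.11 (95% interval -0.16 to 0.33, edgeR adjusted p = 0.685). Of the 15 estrogen-induced genes with no called difference, 12 had a 95% interval within a 1.5-fold difference.

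Estrogen-repressed genes were lower with GNE-858 than with GDC-9545 in 9 of 12 members (10 adjusted over the list alone). The median was -0.36 (camera adjusted p = 3.55e-14, and adjusted p = 0.0305 with an estimated correlation), and 5 and 4 were lower without GDC-9545 replicates 1 and 2. BAK1 differed by -0.79 ± 0.06 and IL1R1 by -1.14 ± 0.09. DNA replication genes were higher with GNE-858 in 32 of 35 members (33 adjusted over the list alone), MCM3 by 0.50 ± 0.05. The median was 0.46 (camera adjusted p = 1.11e-34, and adjusted p = 0.0130 with an estimated correlation). Ribosome biogenesis genes were higher in 15 of 26 members (20 adjusted over the list alone), DDX21 by 0.44 ± 0.05. The median was 0.25 (camera adjusted p = 3.46e-11, and adjusted p = 0.0305 with an estimated correlation), and 9, 9 and 6 were higher without DMSO replicate 2, GDC-9545 replicate 1 and GDC-9545 replicate 2. Mitosis genes were higher in 8 of 30 members (16 adjusted over the list alone), CDK1 by 0.38 ± 0.06. The median was 0.16 (camera adjusted p = 3.75e-06, and adjusted p = 0.286 with an estimated correlation). Their number was 5 without either DMSO library, 4 and 3 without GDC-9545 replicates 1 and 2, and 19 without GNE-858 replicate 2. MKI67 differed by 0.34 ± 0.07 (edgeR adjusted p = 0.00993, and 0.0665 at 0.28 without GDC-9545 replicate 1).

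Other lists also differed between the compounds. Interferon-stimulated genes were lower in 7 of 27 members (11 adjusted over the list alone), OAS1 by -0.68 ± 0.10. The median was -0.19 (camera adjusted p = 1.36e-05, and adjusted p = 0.180 with an estimated correlation), and 4 and 11 were lower without GDC-9545 replicate 2 and GNE-858 replicate 2. RNAs without a poly(A) tail were lower in 5 of 13 (7 adjusted over the list alone), H2BC21 by -0.41 ± 0.05. The median was -0.41 (camera adjusted p = 3.57e-05, and adjusted p = 0.286 with an estimated correlation), and 3, 3, 2 and 3 were lower without DMSO replicate 1, DMSO replicate 2, GDC-9545 replicate 1 and GNE-858 replicate 1. Cholesterol efflux genes were lower in 2 of 8 (3 adjusted over the list alone), ABCG1 by -1.01 ± 0.07. The median was -0.22 (camera adjusted p = 0.00171, and adjusted p = 0.180 with an estimated correlation), and 1 was lower without any single DMSO or GDC-9545 library. Mitochondrially encoded transcripts were lower in 1 of 13 (3 adjusted over the list alone). The median was -0.16 (camera adjusted p = 0.00487, and adjusted p = 0.542 with an estimated correlation). Without GNE-858 replicate 2 that median was -0.03 and its adjusted p 0.153, with 3 members lower, 10 were lower without GNE-858 replicate 1, and the call of the 1 was lost without GDC-9545 replicate 2. Fry did not call that list (adjusted p = 0.258). The mitochondrial share was 1.40% in GNE-858 replicate 1 and 1.11% in GNE-858 replicate 2. ERK feedback genes were higher in 5 and lower in 2 of 15 (5 and 3 adjusted over the list alone), the stress-induced gene IER3 by 1.23 ± 0.11. The median was 0.26 (camera adjusted p = 0.00779, and adjusted p = 0.180 with an estimated correlation), and 3 were higher without GDC-9545 replicate 2. The number lower was 1 without DMSO replicate 2, and both calls were lost without DMSO replicate 1, either GDC-9545 library or GNE-858 replicate 1. Cholesterol synthesis genes were higher in 5 and lower in 1 of 24 (14 and 2 adjusted over the list alone). The median was 0.17 (camera adjusted p = 0.00705, and adjusted p = 0.180 with an estimated correlation). The number higher was 2 without either DMSO library, 3 without GDC-9545 replicate 1 and 12 without GNE-858 replicate 2, and all 5 calls were lost without GDC-9545 replicate 2. The call of the gene that was lower was lost without either DMSO library or GDC-9545 replicate 2, and 3 were lower without GNE-858 replicate 2. HMGCS1 differed by 0.19 ± 0.06 (edgeR adjusted p = 0.0802, and 0.00508 at 0.26 without GNE-858 replicate 2) and LDLR by 0.01 ± 0.05 (edgeR adjusted p = 0.953).

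Camera called no difference between the compounds for the other lists. Adjusted p was 0.552 for luminal genes (1 higher and 5 lower), 0.111 for basal and mesenchymal genes (0 called by edgeR, 3 at an unadjusted p under 0.05) and 0.108 for stromal, endothelial and blood genes (0 called by edgeR, 2 at an unadjusted p under 0.05), 0.0930 for fatty acid synthesis (3 higher, ELOVL5 by 0.49 ± 0.06), 0.254 for endoplasmic reticulum stress (1 higher), 0.0696 for heat shock (3 higher) and 0.952 for ATF4 stress genes (2 higher and 1 lower, with MTHFD2 higher by 0.40 ± 0.06). The ATF4 list had a median of -0.03 and a mean and test in the other direction. Adjusted p was 0.526 for aryl hydrocarbon receptor targets (1 lower), with a median of 0.08 against a mean of -0.23 and a lower test direction, and 0.723 for retinoic acid targets (1 higher and 2 lower), with a median of -0.19, a mean of 0.13 and a lower test direction. It was 0.505 for NRF2 targets (4 higher and 1 lower), 0.552 for p53 targets (1 higher and 2 lower), 0.505 for glucocorticoid, progestin and androgen targets (1 higher and 2 lower), 0.0771 for hypoxia and glycolysis (6 higher and 3 lower, with SLC2A1 higher by 0.55 ± 0.05), 0.339 for lysosome genes (1 higher and 3 lower) and 0.611 for nuclear oxidative phosphorylation (0 called by edgeR, 5 at an unadjusted p under 0.05). Cytosolic ribosomal protein genes (1 lower, adjusted p = 0.0745) were called lower without GDC-9545 replicate 2 (adjusted p = 0.0121) and without GNE-858 replicate 2 (adjusted p = 1.12e-05). Camera also called stromal, endothelial and blood genes without GDC-9545 replicate 1 (adjusted p = 0.0473), and heat shock genes (adjusted p = 0.0242) and hypoxia and glycolysis genes (adjusted p = 0.0322) without GNE-858 replicate 1. Adjusted over the list alone, the numbers higher and lower were 2 and 7 for luminal, 6 and 0 for fatty acid, 2 and 0 for endoplasmic reticulum stress, 5 and 0 for heat shock, 4 and 3 for ATF4, 0 and 1 for aryl hydrocarbon receptor, 2 and 4 for retinoic acid, 4 and 1 for NRF2, 1 and 2 for p53, 8 and 3 for hypoxia and 0 and 1 for ribosomal protein genes.

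Several of these lists were called in other settings. Camera called fatty acid synthesis (adjusted p = 0.0380), heat shock (0.0282) and hypoxia and glycolysis genes (0.0148) with the GC content and length offset, and luminal (0.0309), fatty acid (0.0242), endoplasmic reticulum stress (0.0350), heat shock (0.00401) and hypoxia and glycolysis genes (0.0190) with no filter. Heat shock genes were also called with DESeq2 (0.0428) and limma-voom (0.0304, and 0.0195 with quality weights), fatty acid synthesis genes with limma-voom (0.0435, and 0.0382 with the weights), and ribosomal protein genes with upper-quartile scaling (0.0368), the stricter filter (0.0388), DESeq2 (0.0428) and limma-voom (0.0435, and 0.0218 with the weights). Fry called fatty acid (0.000949), endoplasmic reticulum stress (0.0263), heat shock (0.000949) and hypoxia and glycolysis genes (0.0118).

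Member counts of these lists also moved when 1 library was left out. The calls of endoplasmic reticulum stress and heat shock genes were lost without DMSO replicate 1, DMSO replicate 2, GDC-9545 replicate 1 or GDC-9545 replicate 2. The numbers higher and lower without DMSO replicate 1 were 1 and 0 for luminal, 2 and 0 for ATF4, 1 and 1 for p53, for glucocorticoid, progestin and androgen and for lysosome, and 4 and 1 for hypoxia genes. Without DMSO replicate 2 they were 1 and 2 for luminal, 1 and 0 for fatty acid, 1 and 1 for p53, for glucocorticoid, progestin and androgen and for lysosome, and 4 and 1 for hypoxia genes. Without GDC-9545 replicate 1 they were 2 and 3 for luminal, 1 and 1 for aryl hydrocarbon receptor, 2 and 1 for p53, 1 and 1 for glucocorticoid, progestin and androgen, 5 and 1 for hypoxia, and 1 and 0 for lysosome and for nuclear oxidative phosphorylation genes. Without GDC-9545 replicate 2 they were 1 and 0 for luminal, fatty acid, ATF4 and lysosome, 1 and 1 for NRF2, retinoic acid, and glucocorticoid, progestin and androgen, 0 and 1 for p53 and 2 and 1 for hypoxia genes. Without GNE-858 replicate 1 they were 1 and 2 for luminal, 3 and 0 for ATF4, 3 and 3 for ribosomal protein and 1 and 0 for nuclear oxidative phosphorylation genes. Without GNE-858 replicate 2 they were 2 and 11 for luminal, 0 and 1 for basal and for stromal, 6 and 2 for fatty acid, 3 and 1 for endoplasmic reticulum stress, 3 and 5 for ATF4 and 5 and 1 for heat shock genes. Without that library they were 1 and 1 for aryl hydrocarbon receptor, 4 and 4 for NRF2, 4 and 5 for p53, 1 and 28 for ribosomal protein, 3 and 5 for lysosome and 3 and 3 for nuclear oxidative phosphorylation genes.

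The largest rises with GNE-858 relative to GDC-9545 were in AGR3 (3.58 ± 0.22), the sialic acid-binding receptor gene CD22 (9.11-fold), the keratin gene KRT13 (8.06-fold), the sodium channel gene SCNN1B (7.29-fold), ATRNL1 (7.26-fold), SLC4A10, CDH26 (2.71 ± 0.22) and RAMP3 (5.85-fold). Among the 10 largest falls were PSCA, ACHE (2.86-fold, -1.51 ± 0.12), the secreted BMP antagonist gene CHRD (-1.31 ± 0.24), MUC3A, IL1R1, the prohormone convertase gene PCSK2 (-1.09 ± 0.09), the monoamine oxidase gene MAOB (-1.05 ± 0.17) and CYP4B1 (-1.02 ± 0.15). In total 2054 genes differed between the compounds, 1383 higher and 671 lower with GNE-858, of which 135 and 42 by over 2-fold (edgeR quasi-likelihood test). The share that was higher, 67.3%, was 56.6% with upper-quartile scaling, 54.5% with the GC content and length offset, 51.5% without GNE-858 replicate 2 (2161 higher and 2034 lower) and 89.1% when a fold above 1.5 was tested. By the estimates against DMSO alone, called or not, 1201 of the 2054 genes had the same sign with both compounds and a smaller size with GNE-858, 761 of them below 0 and 440 above 0. A further 112 had the same sign and a larger size with GNE-858, and 741 had opposite signs. The count was 1107 and 1128 without DMSO replicates 1 and 2, 636 without GDC-9545 replicate 2, 4195 without GNE-858 replicate 2, 3193 with no filter, 3223 with a replicate block, 1087 with the 2 groups alone, 3257 with the offset, 730 at a threshold of 0.01 and 92 when a fold above 1.5 was tested. In a further 3699 genes called with GDC-9545 against DMSO no difference was called, which does not show that the compounds acted alike on them.

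**Figure D3:**
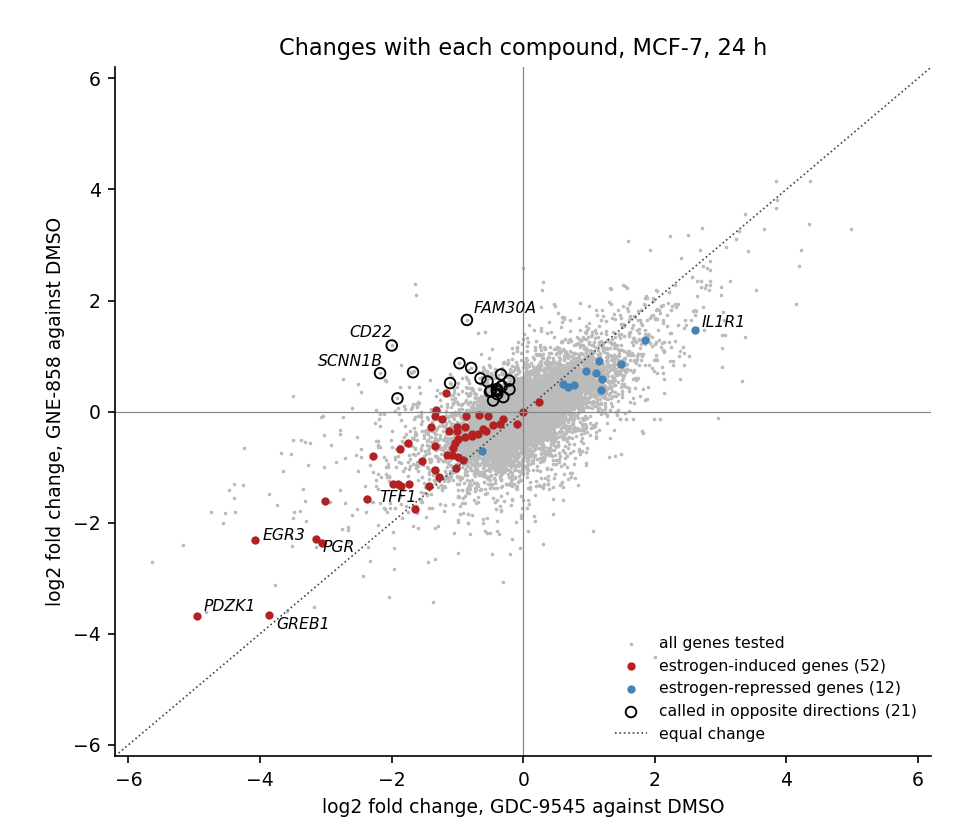
Log2 fold change against DMSO with GDC-9545 (x axis) and GNE-858 (y axis) for the tested genes (grey, with 9 outside the drawn range of 6.2), the 52 estrogen-induced genes (red), the 12 estrogen-repressed genes (blue) and the 21 genes called in opposite directions (rings). The dotted line marks equal change, and most red points lie above it, with the list's medians at -1.15 on the x axis and -0.56 on the y axis.

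Both compounds were then compared through the genes they share. Of the estrogen-induced genes, 40 fell with both compounds, 9 were called lower with GDC-9545 alone and 0 with GNE-858 alone. CA12 and GFRA1 were among the 9 and differed between the compounds, with the differences given before. Over all genes, 2102 were called in the same direction with both, 1037 higher and 1065 lower, including TNFSF10, SALL4, PDZK1 and CXCL12. Independent lists of these sizes would share 195.1 and 195.7, and simulated unchanged groups against the same DMSO libraries shared 0.2 on average and at most 2. With no gene changed in that simulation, almost none could be called. It therefore cannot show how much the shared DMSO libraries add to the overlap of genes that do change. The correlation of the fold changes across genes, which are not independent replicates, was 0.676 against 0.497 simulated, and the same sign was found for 75.1% of genes against 66.8%. The covariance was 0.189 against 0.0485 simulated, a difference of 0.141. Part of the excess in the overlap may come from the shared controls, which could not be split. The count of 2102 was 557 and 487 without DMSO replicates 1 and 2, 3921 with the GC content and length offset, 820 at a threshold of 0.01 and 92 when a fold above 1.5 was tested.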

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

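The offset for GC content and length was chosen after the data were seen. Leaving out each library was planned, but the fit without GNE-858 replicate 1 was chosen as a test of this pattern only after its result was seen.

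Of the genes called with both compounds against DMSO, 21 were lower with GDC-9545 and higher with GNE-858, none the other way round. In all 21 the difference between the compounds was itself called by edgeR. Choosing genes called on opposite sides of the same DMSO libraries makes that nearly certain, so it is no independent support. The 21 genes drew attention because the effects differed by a direct test. CD22 fell by 2.00 ± 0.18 with GDC-9545 (SE) and rose by 1.19 ± 0.14 with GNE-858, going from 2.95 ± 0.290 CPM with DMSO to 0.735 ± 0.103 and 6.74 ± 0.195 CPM (SD, n = 2). FAM30A, a long non-coding RNA gene, was at -0.86 ± 0.16 and 1.65 ± 0.14, and ARHGEF28, which encodes a RhoA exchange factor, at -0.97 ± 0.15 and 0.87 ± 0.13. The sodium channel subunit gene SCNN1B was at -2.17 ± 0.18 and 0.69 ± 0.15, but without DMSO replicate 2 its rise with GNE-858 was 0.52 with an adjusted p of 0.145. SCNN1G, which encodes another subunit of that channel and was named after its values were seen, was at -1.11 ± 0.15 and 0.51 ± 0.14, and the adjusted p of its rise was 0.178, 0.171, 0.0598 and 0.0585 without DMSO replicate 1, DMSO replicate 2, GNE-858 replicate 1 and GNE-858 replicate 2. ARHGEF28 was likewise named after its values were seen.

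The number of genes called in opposite directions varied with the libraries and settings used. It was 5 and 3 without DMSO replicates 1 and 2, 39 without GDC-9545 replicate 1 and 92 without GNE-858 replicate 2. With the offset for GC content and length it was 63, with no filter 54, with a replicate block 47, at a threshold of 0.01 it was 5 and when a fold above 1.5 was tested 1. In simulated unchanged groups against the same DMSO libraries it was 0, but with no gene changed there, almost none could be called. A GC content or length trend between the libraries was weighed against a response that differs between the compounds. With an offset for both, 21 of the 21 genes were still called in opposite directions, with the median log2 fold change of GNE-858 going from 0.51 to 0.41 and that of GDC-9545 from -0.51 to -0.45, which argues against that trend as the whole cause. For a fault of the GNE-858 replicate 1 library alone, the fit without it was used. The median of the 21 genes for GNE-858 was then 0.48, and 0.43 without GNE-858 replicate 2. The 21 had been called with both libraries in the fit, so a rise in each library was largely set by that choice. A fault of 1 library is thus left open. A compound-specific response may account for part of these genes, as a hypothesis found and tested on the same data.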

How the results depend on the processing

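The offset for GC content and length and the library quality weights were chosen after seeing the data, and the other alternatives were planned. The estrogen-induced list stayed called in every setting in which lists were tested. Its median lay between -1.16 and -1.12 with GDC-9545, -0.58 and -0.52 with GNE-858 and 0.45 and 0.55 between the compounds. Lists were not tested in the fits of the 2 groups alone, at the minimum fold of 1.5 or at the threshold of 0.01. Of these settings, only the fits of the 2 groups alone were run for the named genes. In GDC-9545 against DMSO, GNE-858 against DMSO and GNE-858 against GDC-9545, 130, 111 and 96 named genes were called. Of these, 114, 59 and 62 kept their call in every single-gene alternative that gave them an adjusted p, and 0 changed sign. A gene left without an adjusted p was not counted as lost. The call was lost in at least 1 of 6 leave-outs by 16, 52 and 34 genes. Of 20, 15 and 11 lists called, 15, 13 and 10 were called in every leave-out and other alternative at the preset correlation, and 4, 4 and 4 with an estimated correlation. In the same order of comparisons, followed by genes shared in the same direction and genes in opposite directions, counts were 508, 103, 92, 92 and 1 at a minimum fold of 1.5 and 3138, 992, 730, 820 and 5 at a threshold of 0.01, by construction. Leaving out 1 library gave 2740 to 6559, 567 to 4574, 636 to 4195, 487 to 2801 and 3 to 92, with the lowest counts without DMSO replicate 2 (GDC-9545 replicate 2 for the compounds) and the highest without GNE-858 replicate 2. With no filter, 3193 genes differed between the compounds and 54 went in opposite directions. In the same order of comparisons, fits of the 2 groups alone gave 6516, 2344 and 1087 genes. The main fit gave 5242, 2843 and 2054. It shared the estimate of spread across the groups, but their replicate pairs differed unequally. Chi-square per gene was 3.72 for DMSO, 9.45 for GDC-9545 and 23.4 for GNE-858. P-values of the main fit may thus be too small for the comparisons with GNE-858 and too large for GDC-9545 against DMSO. The offset gave 4793 genes for GNE-858 against DMSO, 3257 between the compounds, 3921 shared and 63 opposite. Leaving out a library also changes the shared estimate of spread. A changed count therefore does not by itself single out that library. In GDC-9545 against DMSO, the GNE-858 libraries enter only through the filter, the scaling and that spread. The cause of the changes with the filter, the left-out libraries and the offset was not tested further. Deviations of same-numbered libraries correlated at 0.00638 for DMSO and GDC-9545, -0.00935 for DMSO and GNE-858 and 0.0997 for GDC-9545 and GNE-858. A replicate block gave 6066, 4110 and 3223 genes in the same order of comparisons, each more than the main fit, and 47 in opposite directions. Apart from the 3223 and the 47, its counts stayed within 1.5 times. Whether the numbers pair the samples is therefore left open. Library quality weights were 1.62 and 1.63 for DMSO, 1.05 and 1.06 for GDC-9545 and 0.582 and 0.585 for GNE-858. Thinning to the smallest library left every count within 1.5 times, and with 2 libraries per group small changes are missed, as 46% of 1.5-fold changes were found in simulated libraries for GDC-9545 against DMSO.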

Other observations

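All tests in this part were chosen only after the results were seen.

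Families of genes with a shared symbol and at least 15 members (111 families) showed groups not covered by the lists. Nucleoporin genes (NUP), whose products build the nuclear pore, fell with GDC-9545 in 16 of 26 members, with a median log2 fold change of -0.34 (camera adjusted p = 2.99e-05, and adjusted p = 0.702 with an estimated correlation). NUP107 fell by 0.64 ± 0.07, NUP155 by 0.60 ± 0.06 and NUP205 by 0.58 ± 0.06 (SE, n = 2 libraries per group). Against GDC-9545, nucleoporin genes were higher with GNE-858 in 11 of 26 members, with a median of 0.21 (camera adjusted p = 1.38e-05, and adjusted p = 0.912 with an estimated correlation), NUP205 by 0.39 ± 0.06. Genes of the large subunit of the mitochondrial ribosome (MRPL) fell in 22 of 51 members and rose in 1 with GDC-9545 (median -0.21, camera adjusted p = 0.00120, and adjusted p = 0.702 with an estimated correlation), and fell in 18 with GNE-858 (median -0.19, camera adjusted p = 3.3e-05, and adjusted p = 0.650 with an estimated correlation). MRPL17 fell by 0.60 ± 0.06 and 0.42 ± 0.06. Zinc finger genes (ZNF) went the other way with GDC-9545, with 88 of 480 higher and 22 lower (median 0.15, camera adjusted p = 0.0184, and adjusted p = 0.746 with an estimated correlation). None of these medians changed direction under DESeq2 size factors or upper-quartile scaling, but nucleoporin genes higher with GNE-858 than with GDC-9545 numbered 7 under the latter. They numbered 6 without either DMSO library, 5 and 3 without GDC-9545 replicates 1 and 2, and 17 without GNE-858 replicate 2. With the offset for GC content and length, the MRPL medians were -0.14 (camera adjusted p = 0.0125) with GDC-9545 and -0.12 (camera adjusted p = 0.00975) with GNE-858, and 140 zinc finger genes were higher. MRPL genes that fell with GDC-9545 numbered 11 and 12 without DMSO replicates 1 and 2, and 1 fell with GNE-858 without either of these libraries. The MRPL gene that rose lost its call without DMSO replicate 1, DMSO replicate 2 or GDC-9545 replicate 2. Zinc finger genes higher and lower with GDC-9545 numbered 35 and 9 without DMSO replicate 1, 37 and 10 without DMSO replicate 2, 54 and 14 without GDC-9545 replicate 1, and 57 and 13 without GDC-9545 replicate 2.

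A smaller response to GNE-858 could be a common fraction of the response to GDC-9545 for every estrogen-induced gene. Against that hypothesis, 32 of 52 genes departed from the median ratio of 0.562 (edgeR test, adjusted over the list alone), 17 lowered more than it predicts and 15 less. That ratio came from the same genes and was taken as exact, so departures on both sides follow from its choice. The test was not repeated with a library left out. GREB1 and TFF1 kept ratios of 0.949 and 0.930 of their GDC-9545 response, while CA12 kept 0.0550, GFRA1 0.106 and STC2 0.351. What sets these genes apart was not tested.

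The GNE-858 libraries differed from each other with a chi-square per gene of 23.4, against 3.72 for DMSO and 9.45 for GDC-9545. A difference in depth is argued against by the ratio of their totals, 1.01, below the 1.04 and 1.09 of the DMSO and GDC-9545 pairs. GC content and length explained 37.8% of the variance of the difference over 14086 genes, against 1.64% for DMSO and 22.2% for GDC-9545, so that a GC trend in one library is a candidate explanation of part of it. A different size of the estrogen response is left open. The estrogen-induced genes differed between these libraries by a median log2 difference of -0.034 (95% interval -0.11 to 0.00, from 2000 resamples of the genes). That interval measures the spread between genes, which are not independent replicates, and not the spread between libraries. The kits named in the protocols are not assigned to libraries, so a difference between kits stays untested.

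Histone genes were higher with GDC-9545 while DNA replication genes were lower: of 51 histone genes, 19 rose and 3 fell (1 without either DMSO library or GDC-9545 replicate 1 and 5 without either GNE-858 library), with a median of 0.41 (camera adjusted p = 0.000634, and adjusted p = 0.702 with an estimated correlation), H2BC8 by 1.15 ± 0.09 and H3C6 by 1.07 ± 0.09. The 3 that fell were H2AZ1 (-0.47 ± 0.06), H2AX (-0.52 ± 0.16) and H2AJ (-0.53 ± 0.14). Their mean log2 CPM was 8.80, 8.07 and 7.95, against 4.24 for H2BC8 and 3.45 for H3C6. H3-3B, the most abundant member at 10.6, was not called (-0.07 ± 0.05). H2BC8 and H3C6 also rose with GNE-858, by 0.48 and 0.73. With the offset for GC content and length the median of the 51 genes was 0.45, which argues against that trend as the cause. More RNA without a poly(A) tail in the GDC-9545 libraries cannot be told apart from a change in histone transcripts. The 25 small RNA genes had a median of -0.28 (95% interval -0.68 to 0.16, from 2000 resamples of the genes). The median was -0.68 for the 15 small nucleolar RNA genes and 0.15 for the 8 miscellaneous RNA genes among them. The 1 small Cajal body RNA gene was at 0.37 and the 1 small nuclear RNA gene at -0.28. Such short RNAs are also partly lost in library preparation.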
